A study of Mus musculus with 4 samples.

How the data were processed

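Single-cell RNA-seq of the retina was measured in 4 libraries, 1 per group, with 10x Chromium v3 reagents on a NovaSeq instrument, per the labels' protocols. Cells came from papain-dissociated retinae, 4 retinae of 2 mice per library, with 15000 cells loaded, per the labels' protocols. Mice were Abca4-/-Rdh8-/- on a C57BL/6J background. Mice of the bleached groups were dark-adapted for 24 h and given 1% tropicamide before light, with the drugs injected 30 min before light in DMSO, per the labels' protocols. These steps were not recorded for the unbleached group, so the bleaching comparison may differ in them too. Cell Ranger 6.0.1, Seurat 3.2.2 and the build mm10 are named, without their roles, per the submitters' processing notes. A further group that the series text mentions was not analysed here. Whether counting used strand or intronic reads, and how reads shared between genes were treated, are not given in the sources used here.

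The deposited values were natural logs of 1 plus UMIs per 10000 UMIs of the cell, from the data slot of an RNA assay, per the file headers. Cells and genes had been filtered by the authors, with thresholds not given in the sources used here. In the values no cell had under 497 genes or over 19.99% mitochondrial UMIs, and every gene was seen in at least 10 cells. Back-transformed values of each cell were whole multiples of its smallest value, so UMIs per cell and gene were recovered, with 100% of values within 0.001 of a whole number, 140410160 UMIs in all. The design had assumed counts, and all counts below are these recovered UMIs. Named genes were ranked by the design's fallback for log-normalized files, the ratio of class means of back-transformed values.

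Depth per library ranged from 28983626 to 44386442 UMIs and median genes per cell from 1810 to 2155. Intervals are exact 95% intervals for counts (Poisson ratio conditional on the sum, or Clopper-Pearson for shares) and cover counting error only. They hold no variation between mice, dissociations or libraries, and those of ratios hold none between cells beyond counting. A count of 0 was replaced by 3 counts for a bound, and log2 ratios used a prior of 0.5 UMIs scaled to the total.

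Cells were clustered with scanpy 1.11.5 (anndata 0.12.19, igraph 0.11.9) on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, which gave 35 clusters. Doublets were called per library with scrublet on 30 components. It called 1, 2, 24 and 11 cells in the unbleached, bleached vehicle, rolipram and BC11-38 libraries, or 0.0176%, 0.0294%, 0.304% and 0.179%, against 4.56%, 5.45%, 6.32% and 4.91% expected from the cell numbers. The caller thus found few of the expected doublets, the called cells were left out, and most doublets remain. An alternative left out the highest scores up to the expected share. After removal 5696, 6807, 7870 and 6132 cells were kept.

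Clusters took the name of the class with the largest share of its markers detected, at least 3 of them. A marker counted as detected when seen in at least 15% of the cluster's cells and at least 2-fold over the median of the other clusters, with 0.1 per 10000 added. Leading genes were ranked by that fold. Shallow clusters without a marker of their class among their 10 leading genes stayed unnamed. The marker lists were fixed before the data were examined, but this fold and its thresholds were set after the clusters were seen. Under a second rule, fold against all other cells, some rod clusters are unnamed. A class was compared between libraries only where none of its clusters had more markers of another class than of its own among the 10 leading genes. The interferon-led rod cluster had none of either kind and was kept. The cluster with more general bipolar than rod bipolar markers there is given as cluster 3. Amacrine cells lay mostly in clusters 21, 31 and 17 in the unbleached and BC11-38 libraries, 9, 22 and 17 in bleached vehicle and 21, 17, 22 and 25 in rolipram, and cones in cluster 14 in all. A class needed 50 cells per library for ratios.

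UMIs were summed per class and library and scaled by the class total. Comparisons were bleached against unbleached vehicle, each drug against bleached vehicle, and rolipram against BC11-38. A gene entered with at least 100 UMIs over both libraries and was counted as different at 2-fold. With 1 library per group no test across samples was run. The number expected from counting noise came from simulated libraries without differences. Gene counts and position sets keep Xist, Tsix and Y-linked genes. In classes other than rods, genes with more CPM in rods than in the class were left out of named genes and list medians as possible free RNA. Gene counts and position sets keep these genes.

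Gene lists were written before the data were examined. A list's value is the median log2 ratio of its counted members, with its percentile among 10000 random lists of the same size matched on mean expression. The lists reported were chosen after their medians were seen. Some genes are in more than 1 list, such as Gfap, which is also an astrocyte marker. List examples are members at least 2-fold different with the largest ratios, or those with most counts. Values of some list members are not reported here.

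Named genes were fixed by rule before the data were examined. They are the genes with the largest ratios in each direction, 6 in rods, 5 in Müller glia, 3 in cones and 3 in cluster 3, and 5 in rods and 4 in Müller glia between the drugs. They needed a mean of 0.5 per 10000 in the higher library and a value above 0 in at least 50 cells. Mitochondrial, ribosomal, haemoglobin, numbered predicted and clone-named genes, names ending in Rik, Xist, Tsix and Y-linked genes were left out. Other X-linked genes were kept. Phosphodiesterase genes that the drugs target, Pde2a, Abca4 and Rdh8 were reported whatever their values. Rnf121, C1qa, Cx3cr1, Edn2, Gfap and Lcn2 were chosen for further values after their values were seen.

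Coordinates came from GENCODE M21 on GRCm38 (mm10), where 98.2% of symbols matched. Of 74 named genes, 37 are overlapped by another gene, 19 on the same strand and 31 on the other, and their counts are uncertain to that extent. Members of the Gbp, Ifit and H2 families have near-identical copies, so their counts are uncertain as well.

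Position of the drug libraries was the median log2 ratio to the unbleached library over genes at least 2-fold different after bleaching. Correlations and covariances across genes were taken between the bleaching ratio and each drug's ratio to bleached vehicle. Because the bleached vehicle library enters both of these ratios, they were also computed on simulated libraries without differences. Correlations were also computed with separate bleached vehicle cells for each ratio. For shares of cells with a UMI, cells were thinned to 750 UMIs in rods and 2000 in other classes, depths set after the median depths were seen, and shallower cells were left out.

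The ratio code was tested on simulated counts drawn from the real means, with 3-fold and 1.5-fold differences planted. For bleaching in rods (8273 genes) it called 100% of 3-fold and 1% of 1.5-fold genes at the 2-fold limit, with 95.6% of intervals holding the planted ratio, and in Müller glia (11212 genes) 100%, 3.03% and 95.3%. For rolipram these values were 100%, 1.02% and 95.4% in rods (8273 genes) and 100%, 0% and 95.5% in Müller glia (11311 genes). For BC11-38 they were 99%, 1.01% and 95.7% in rods (8178 genes) and 99%, 4% and 95.4% in Müller glia (11067 genes). Between the drugs they were 100%, 1% and 95.5% in rods (8098 genes) and 100%, 0% and 95.8% in Müller glia (9519 genes).

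Alternatives fixed before the data were examined were TMM scaling, minima of 30 and 300 UMIs, a 1.5-fold limit, the mean over cells of counts per 10000, the class mean of the log values, doublets kept, Leiden resolutions 0.5 and 2, cells with at least 500 UMIs and at most 10% mitochondrial UMIs, shares of non-rod cells, genes higher in rods kept, cells thinned for the named genes, and position genes chosen and measured on separate cells. Chosen after the data were seen were thinning for the gene counts, the unnamed cluster counted as rods, cells with Y-linked and no Xist UMIs, cells without the highest doublet scores and the second naming rule. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9, and TMM factors were computed in numpy.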

Results

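Retinal transcripts were counted cell by cell in Abca4-/-Rdh8-/- mice, which lack a transporter and a dehydrogenase that clear all-trans-retinal from photoreceptors and whose photoreceptors are damaged by bright light. The 4 groups had 1 library each, so no value below has a replicate, and each library pooled 4 retinae from 2 mice aged 6 weeks. The unbleached vehicle group was kept from bright light. The bleached vehicle group was exposed to white light of 10000 lux for 30 min, and the other 2 groups were exposed in the same way after 2 mg/kg of rolipram, an inhibitor of phosphodiesterase 4, or of BC11-38, an inhibitor of phosphodiesterase 11. Retinae of the bleached groups were collected 1 day after light. The design asks which transcripts differ after photobleaching and where each inhibitor, given before light, leaves them.

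The unbleached vehicle, bleached vehicle, rolipram and BC11-38 libraries had 5697, 6809, 7894 and 6143 cells, with 35495396, 44386442, 31544696 and 28983626 UMIs (unique molecular identifiers, 1 per captured transcript). Median UMIs per cell were 4585, 4324, 3443 and 4102 in the same order. The libraries also differed in sex make-up. Xist was seen in 48.1% of unbleached, 0.176% of bleached vehicle, 51.6% of rolipram and 48.8% of BC11-38 cells, and Y-linked transcripts in 39.2%, 64.8%, 33.5% and 40.5%. Every ratio to the bleached vehicle library therefore sets a library with almost no Xist-positive cells against 1 with many.

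Clustering gave rod-like, cone-like, Müller-like, amacrine-like, bipolar-like, horizontal-like and microglia-like cells, named below without the suffix. At Leiden resolution 0.5 a separate astrocyte-like cluster of 60 cells also took the Müller name. It held 9, 23, 21 and 7 cells of the unbleached, bleached vehicle, rolipram and BC11-38 libraries. Its 10 leading genes, Gfap, S100b and Serpina3n among them, held 2 astrocyte markers and 1 Müller marker. Müller shares were the same at resolution 1, so the Müller class below likely includes these cells. Müller glia made up 10.5% of unbleached cells (exact 95% interval 9.68 to 11.3%), 20.7% of bleached vehicle cells (19.7 to 21.7%), 15.4% of rolipram cells (14.6 to 16.2%) and 9.78% of BC11-38 cells (9.05 to 10.6%). Amacrine cells ran the other way, with 21.3% (20.3 to 22.4%), 7.35% (6.74 to 7.99%), 14.6% (13.8 to 15.4%) and 17.5% (16.5 to 18.4%). Among non-rod cells the same orders were seen, at 18.0%, 32.8%, 23.1% and 15.6% for Müller glia and 36.6%, 11.6%, 22.0% and 27.9% for amacrine cells. Rods were 34.8% (33.5 to 36.0%), 28.9% (27.8 to 30.0%), 32.4% (31.3 to 33.4%) and 37.1% (35.9 to 38.4%). A cluster of shallow cells with rod markers stayed unnamed and held 6.95%, 7.89%, 1.16% and 0.228% of the libraries. With it counted as rods, an alternative chosen after the data were seen, the rod shares of the 4 libraries were 41.7%, 36.8%, 33.5% and 37.4%, so their order is not settled.

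Microglia were few in every library and absent from 1 of them. There were 14 microglia-like cells (0.246%, 0.134 to 0.412%) in the unbleached, 38 (0.558%, 0.395 to 0.765%) in the bleached vehicle and 32 (0.407%, 0.278 to 0.574%) in the rolipram library, and 0 of 6132 cells in the BC11-38 library, which allows a share of up to 0.0489%. Over whole libraries, C1qa, a complement gene of microglia, stood at 26.0, 36.5, 39.0 and 0.0690 CPM (counts scaled to the total), the last from 2 UMIs. Cx3cr1, the fractalkine receptor, stood at 11.9, 13.9, 16.5 and 0.104 CPM. All 13 microglial markers were lowest in the BC11-38 library, with a median of 0.104 CPM against 9.35, 13.9 and 16.5. Many of these cells had high doublet scores in the unbleached and rolipram libraries. Without the highest scores, chosen after the data were seen, the unbleached, bleached vehicle and rolipram shares were 0.0552%, 0.435% and 0.0676%. No class ratios were taken from microglia, because no library had 50 of them.

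After bleaching, rods had higher interferon-response transcripts and slightly lower phototransduction transcripts. Gbp7, a guanylate-binding protein, stood at 71.8 CPM in bleached rods against 13.2 CPM in unbleached rods, 5.43-fold higher (95% counting interval 4.004 to 7.50; mm10 chromosome 3, 142530342 to 142550149). Ddx58, which encodes the RNA sensor RIG-I, was 5.37-fold higher (3.97 to 7.39; chromosome 4, 40203773 to 40239828), Igtp 4.02-fold (2.91 to 5.63) and Rtp4 4.01-fold (2.93 to 5.59). Oasl2 was 3.88-fold higher (2.85 to 5.38) and Irgm1, an immunity-related GTPase, 3.72-fold (2.98 to 4.70; chromosome 11, 48861968 to 48871683). Among the named genes, lower differences were smaller. Ip6k2, an inositol hexakisphosphate kinase, stood at 189 against 388 CPM, 2.06-fold lower (1.88 to 2.26; chromosome 9, 108783796 to 108806337). Nmt1 was 1.66-fold, Gria2 1.59-fold, Rabgef1 1.58-fold, Sik2 1.55-fold and Negr1 1.54-fold lower. Unbleached amacrine cells held 741 CPM of Gria2 and 283 CPM of Negr1, against 63.8 and 111 CPM in unbleached rods. Ip6k2, Nmt1, Rabgef1 and Sik2 stood higher in rods than in amacrine cells. Amacrine shares were lower after bleaching, so a smaller part from free RNA was not excluded for Gria2 and Negr1.

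Of 16 counted members of the interferon and antigen presentation list, 14 were at least 1.5-fold higher in bleached rods and 0 were that much lower. Their median log2 ratio was 1.15 (counting interval 1.04 to 1.37), at percentile 100 of 10000 random lists matched on expression. Irf7 stood at 166.5 against 54.5 CPM, Stat2 at 187 against 63.8 CPM and Bst2 at 197 against 89.97 CPM. Of 15 immediate early genes, 9 were at least 1.5-fold higher (median 0.68, 0.54 to 0.77), among them Nr4a1 at 68.0 against 30.9 CPM and Junb at 1013 against 519 CPM. Of 10 CREB target genes 6 were higher (median 0.66, 0.55 to 0.74), and most of these 6, such as Fos at 1872 against 1134 CPM, are also immediate early genes. The 21 rod phototransduction genes had a median of -0.32 (-0.34 to -0.29), with all 21 within 1.5-fold and Gngt1, a transducin subunit, at 6049 against 7412 CPM. The 13 mitochondrially encoded transcripts had a median of -0.34 (-0.36 to -0.29), the 19 outer segment and photoreceptor transcription factor genes -0.17 (-0.20 to -0.09) and the 16 heat shock genes -0.28 (-0.36 to -0.14). Cryab, a small heat shock protein, went against its list at 70.7 against 22.8 CPM. It is also among the 10 leading genes of the lens-like cluster and of a Müller cluster. Lens-like cells numbered 4 in the bleached vehicle and 0 in the unbleached library, and free RNA in rods was not tested for Cryab.

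In all, 122 genes were at least 2-fold higher and 9 lower among 8310 genes counted in rods, where counting noise alone gives 0.25, and under scaling by a trimmed mean of ratios (TMM) these were 78 and 13. Xist and Tsix, its antisense transcript, are 2 of the 9, and Eif2s3y and Kdm5d, both Y-linked, are among the 122. Cluster 0 held most bleached rods, clusters 0 and 18 most unbleached rods, and cluster 18 most rods of both drug libraries. A smaller rod cluster was led by interferon genes, among them Irf7, Bst2, Irgm1, Gbp7, Oasl2 and Ddx58, and the values above are over the whole class. In rods with Y-linked and no Xist UMIs the count was 43 genes and the interferon median 0.50 over 8 members, against 1.11 for the same 8 in all rods, and Gria2 lay the other way, with a log2 ratio of 0.22. Under a second rule for naming clusters, which leaves out that interferon-led cluster and cluster 1, a larger one, the count was 70 and the interferon median 1.00. Both alternatives were chosen after the data were seen.

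Müller glia of the bleached vehicle library had higher cell death list transcripts and lower homeostasis and clock transcripts than those of the unbleached library. Hmga2, a chromatin protein of proliferating and embryonic cells, stood at 97.8 against 4.45 CPM, 22.0-fold higher (15.7 to 31.8; chromosome 10, 120361275 to 120476469). Cdsn was 12.8-fold higher (9.42 to 17.7), Kitl, the ligand of Kit, 6.87-fold (5.73 to 8.32), Hbegf, an EGF-family ligand, 6.60-fold (5.62 to 7.80) and Fosl1, an AP-1 subunit, 5.91-fold (4.82 to 7.30). Glul, the glutamine synthetase that recycles glutamate, stood at 1178 against 4005 CPM, 3.40-fold lower (3.34 to 3.46; chromosome 1, 153899944 to 153909723). Shisal2b was 3.89-fold lower (3.45 to 4.38), Cmtm5 3.40-fold (2.99 to 3.86), Pde10a, a phosphodiesterase, 3.19-fold (2.78 to 3.65) and Spc25 3.03-fold (2.95 to 3.12).

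Of 18 Müller homeostasis genes, 8 were at least 1.5-fold lower after bleaching and 0 higher (median -0.43, -0.46 to -0.40; percentile 0), with Hes1 at 516 against 1123 CPM and Abca8a at 313 against 670 CPM. Of 11 circadian clock genes 8 were lower (median -0.67, -0.84 to -0.62), such as Ciart at 34.5 against 89.5 CPM. Of 14 cell death genes 8 were higher (median 0.62, 0.51 to 0.72), with Gadd45b, a stress-response gene, at 424 against 150 CPM. The 22 gliosis and STAT3-response genes went both ways, with 5 higher and 3 lower (median 0.17, 0.16 to 0.23). Among them Lif, a cytokine that acts through STAT3, stood at 62.3 against 10.5 CPM and Tnfrsf12a at 314 against 88.3 CPM, whereas Ccn2 stood at 109 against 372 CPM. The interferon list was close to even in Müller glia (median 0.09, -0.03 to 0.21; 2 of 15 higher), as was the unfolded protein and integrated stress list (-0.02, -0.05 to 0.05; 4 of 18 higher and 1 lower), although its member Asns stood at 78.8 against 16.1 CPM. Medians were -0.39 (-0.49 to -0.32) for 11 glycolysis genes, 0.20 (0.13 to 0.24) for 11 heat shock genes and -0.23 (-0.42 to -0.13) for 5 complement genes. Of 11205 genes counted, 271 were at least 2-fold higher and 193 lower, against 1.5 from counting noise. Cluster 10 held most Müller glia of both vehicle libraries and cluster 13 most of both drug libraries. Glul and Spc25 are among the leading genes of cluster 13, and Crym and Cebpd of cluster 10.

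In cones, Tnfrsf12a, the receptor of the cytokine TWEAK, was 7.28-fold higher after bleaching (5.64 to 9.52), Rbp4, the plasma retinol carrier, 8.09-fold (4.85 to 14.3) and Hecw2 23.0-fold, from 83 against 4 UMIs (8.66 to 86.5). Zdhhc14 was 2.41-fold lower (1.66 to 3.56), Hopx 2.25-fold (1.92 to 2.64) and Gzmm 1.92-fold (1.71 to 2.17). Of 13 cone phototransduction genes 3 were at least 1.5-fold lower and 0 higher (median -0.29, -0.32 to -0.26), with the opsin Opn1sw at 4286 against 7391 CPM. Of 10 immediate early genes 4 were higher (median 0.41, 0.31 to 0.55), including Atf3 at 124 against 25.5 CPM, and the 13 mitochondrially encoded transcripts had a median of -0.52 (-0.56 to -0.49; 4 lower). Of 5358 genes, 70 were at least 2-fold higher and 7 lower, 56 and 12 under TMM scaling, and 28 in all in cells with Y-linked and no Xist UMIs. Cluster 3, which carried rod bipolar and general bipolar markers and is given by its number, had Il27 5.21-fold (3.41 to 8.30), the growth factor Fgf2 3.54-fold (2.52 to 5.10) and Serpina3n, an acute-phase protease inhibitor, 3.09-fold higher (2.70 to 3.55; 374 against 121 CPM). In it Spred1 was 2.91-fold (2.12 to 4.02), Pde10a 2.56-fold (2.00 to 3.30) and Tmeff1 2.19-fold lower (1.64 to 2.94). Its 42 nuclear oxidative phosphorylation genes had a median of 0.21 (0.17 to 0.24) and its 14 clock genes -0.32 (-0.38 to -0.24), and 73 of 6775 genes were at least 2-fold higher and 27 lower.

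With rolipram, interferon-response transcripts in rods were far lower than in bleached vehicle rods, and in Müller glia homeostasis and clock transcripts were higher and cell death list transcripts lower. In rods Igtp and Rtp4 had 0 UMIs against 174 and 181, at least 62.6-fold and 65.1-fold lower when 3 counts stand for 0. Gbp7 was 88.1-fold lower, from 3 against 245 UMIs (29.8 to 430.1), Irgm1 90.6-fold, from 4 against 336 (35.1 to 334), Parp9 124-fold, from 2 against 230 (34.0 to 1030.4) and Oasl2 39.3-fold, from 5 against 182 (16.5 to 122). Sv2c, a synaptic vesicle protein, was 10.3-fold higher (6.43 to 17.4; 57.4 against 5.57 CPM), Gstp1 2.41-fold (1.94 to 3.01), Slc22a29 2.38-fold (1.89 to 3.01), Mylk 2.24-fold (1.80 to 2.79), Rabgef1 2.18-fold (2.03 to 2.34) and Gria2 2.10-fold (1.71 to 2.58). Both genes are also transcribed in amacrine cells, where the rolipram library had 43.2 CPM of Sv2c and 762 CPM of Gria2, against 57.4 and 84.3 CPM in its rods.

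All 11 counted members of the interferon list were at least 1.5-fold lower in rolipram rods, with a median log2 ratio of -4.31 (-4.80 to -3.93), the same with 3 counts in place of 0. Bst2 stood at 9.79 against 197 CPM and Irf7 at 10.9 against 166.5 CPM. The median was -3.25 in cells with Y-linked and no Xist UMIs and -2.32 under the second naming rule, both chosen after the data were seen. Of 15 immediate early genes 11 were lower (median -0.98, -1.08 to -0.83), such as Junb at 211 against 1013 CPM and Atf3 at 34.8 against 108 CPM, and 5 of 10 CREB target genes were lower (median -0.60, -0.75 to -0.52). Rod phototransduction genes had a median of 0.39 (0.37 to 0.43), with 4 of 21 at least 1.5-fold higher. Outer segment and transcription factor genes had 0.23 (0.16 to 0.28; 2 of 19 higher and 1 lower), mitochondrially encoded transcripts 0.36 (0.31 to 0.41; 3 of 13 higher) and heat shock genes -0.26 (-0.37 to -0.17; 4 of 16 lower). Of 8300 genes, 38 were at least 2-fold higher and 231 lower, and 160 in all in cells with Y-linked and no Xist UMIs.

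In rolipram Müller glia Glul stood at 8676 against 1178 CPM, 7.36-fold higher (7.25 to 7.47). Etnppl, an enzyme of phosphoethanolamine breakdown, was 10.1-fold higher (8.09 to 12.7), Syt10 8.94-fold (7.43 to 10.8), Spc25 6.58-fold (6.42 to 6.74) and Omg 5.88-fold (5.02 to 6.90). Gpnmb, a glycoprotein of phagocytic cells, was 95.6-fold lower (51.9 to 199.5; chromosome 6, 49036546 to 49070929), Hmga2 63.9-fold (35.6 to 128), Cdsn 51.6-fold (28.0 to 108), Kitl 21.9-fold (15.8 to 31.4) and Hmox1, a haem oxygenase of the oxidative stress response, 15.6-fold (11.7 to 21.2). Of 18 homeostasis genes 12 were at least 1.5-fold higher and 1, Crym, lower (median 1.07, 1.04 to 1.09), and 10 of 12 clock genes were higher (0.92, 0.84 to 1.02), with Hlf at 432 against 130.4 CPM. Of 22 gliosis genes 12 were lower and 2 higher (-0.65, -0.75 to -0.58), with Lcn2, an iron-binding acute-phase protein, at 58.4 against 360.4 CPM and Timp1, a metalloproteinase inhibitor, at 11.3 against 126 CPM. Of 14 cell death genes 10 were lower and 1 higher (-0.88, -0.99 to -0.77), as were 12 of 18 unfolded protein and stress genes (-0.84, -0.88 to -0.76), Asns among them at 6.82 against 78.8 CPM, and 7 of 11 heat shock genes (-0.64, -0.73 to -0.59). Of 14 glycolysis genes 7 were higher and 1 lower (0.51, 0.40 to 0.61), with the lactate carrier Slc16a1 at 180 against 77.4 CPM.

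The Müller interferon list went both ways with rolipram, 3 of 18 higher and 4 lower (median 0.22, 0.08 to 0.29), with Ifit1 at 97.1 against 33.4 CPM and Ifitm3 at 166 against 374 CPM, and the median was 0.0011 under TMM scaling and -0.16 when genes higher in rods were kept, so its side is not settled. The 5 complement genes had a median of -0.77 (-0.94 to -0.58; 3 lower and 1 higher). A small Müller cluster was led by Rsad2, Ifit3 and Ifit1. Of 11323 genes, 952 were at least 2-fold higher and 668 lower, and under TMM scaling the split was 564 and 1060. That scaling differed from the class totals by 0.22 on the log2 scale here and by 0.24 for BC11-38 in Müller glia. Elsewhere it was over 0.1 in size for bleaching in rods and cones (0.12 in each) and for BC11-38 in rods (-0.17) and cones (-0.11), and ratios are given relative to the class totals.

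Rolipram cones had Gzmm 2.85-fold (2.55 to 3.19), Rab11fip5 3.70-fold (2.31 to 6.14) and Ccdc30 2.55-fold higher (1.75 to 3.77). Tnfrsf12a was 41.7-fold lower (23.1 to 84.1), Rab3b 97.1-fold, from 1 against 96 UMIs (17.02 to 3875), and Hecw2 42.0-fold, from 2 against 83 (11.3 to 352). Cone phototransduction genes had a median of 0.46 (0.42 to 0.49; 6 of 13 higher), with the opsin Opn1mw at 5203 against 2295 CPM, immediate early genes -0.68 (-0.80 to -0.53; 5 of 10 lower) and mitochondrially encoded transcripts 0.24 (0.19 to 0.29; 1 of 13 higher). Of 5288 genes 41 were at least 2-fold higher and 142 lower. In cluster 3, Mir670hg was 3.75-fold (2.84 to 4.99), Pde10a 3.22-fold (2.57 to 4.06) and Ldb2 3.04-fold higher (2.63 to 3.53), Serpina3n 52.5-fold lower (33.5 to 87.5), Prph 49.6-fold, from 3 against 203 UMIs (16.7 to 243), and Atf3 13.01-fold lower (8.55 to 20.8). Its clock genes had a median of 0.11 (-0.08 to 0.20) and its oxidative phosphorylation genes -0.10 (-0.13 to -0.07), and 79 of 7140 genes were at least 2-fold higher and 135 lower.

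With BC11-38, most lists lay on the same side of bleached vehicle as with rolipram, and gliosis and interferon transcripts of Müller glia were close to undetected for several genes. In rods Irgm1, Gbp7, Parp9, Bcl3, Irf1 and Igtp had 0 UMIs against 174 to 336, at least 119-fold, 86.5-fold, 81.2-fold, 79.5-fold, 65.0-fold and 61.5-fold lower when 3 counts stand for 0. Col4a3, a basement membrane collagen chain, was 14.5-fold higher (8.45 to 27.0; chromosome 1, 82586921 to 82722059), Rnf121, a ubiquitin ligase, 6.08-fold (4.97 to 7.48; chromosome 7, 102019137 to 102065469), Hist3h2a 4.52-fold (3.89 to 5.28), Cd52 3.95-fold (2.81 to 5.68), Hcls1 3.91-fold (2.77 to 5.65) and Gria2 3.09-fold (2.55 to 3.77). Gria2 stood at 776 CPM in amacrine cells of the BC11-38 library against 124 CPM in its rods, so free RNA was not excluded here either. All 11 counted interferon genes of rods were lower (median -5.46, -7.65 to -4.35; -5.29 with 3 counts in place of 0). That median was -3.47 in cells with Y-linked and no Xist UMIs and -2.94 under the second naming rule. Bst2 was 238-fold lower, from 3 against 673 UMIs, with 0.830 against 197 CPM.

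Of 15 immediate early genes 13 were lower in BC11-38 rods (median -1.23, -1.41 to -1.10), with Junb at 78.9 against 1013 CPM. CREB target genes had a median of -0.69 (-0.85 to -0.63; 5 of 10 lower and 1 higher), rod phototransduction genes 0.60 (0.55 to 0.61; 11 of 21 higher), outer segment and transcription factor genes 0.38 (0.28 to 0.41; 3 of 19 higher and 2 lower), mitochondrially encoded transcripts 0.39 (0.31 to 0.42; all 13 within 1.5-fold) and heat shock genes 0.02 (-0.08 to 0.11; 2 of 16 lower). Of 8190 genes, 87 were at least 2-fold higher and 352 lower, 139 and 264 under TMM scaling, and 290 in all in cells with Y-linked and no Xist UMIs.

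In BC11-38 Müller glia Pde10a stood at 401 against 19.6 CPM, 20.5-fold higher (18.3 to 22.9; chromosome 17, 8525372 to 8986648). Slco1c1, a thyroid hormone transporter, was 17.1-fold higher (13.6 to 21.7), Arrdc2 16.9-fold (13.6 to 21.2), Etnppl 16.8-fold (13.5 to 21.2) and Zbtb16 11.5-fold (9.32 to 14.3), and Glul stood at 10930 CPM. Gpnmb, Timp1, Fosl1 and Cdsn had 0 UMIs against 1469 to 2722, at least 183-fold, 173-fold, 106-fold and 98.7-fold lower when 3 counts stand for 0, and Serpina3n was 210.2-fold lower, from 5 against 5211 UMIs (90.005 to 648; chromosome 12, 104406729 to 104414329). Of 22 gliosis genes 18 were lower and 1 higher (median -1.93, -2.09 to -1.72), with Lcn2 at 2.18 against 360.4 CPM. Of 12 interferon genes 11 were lower (-2.32, -2.45 to -1.99), such as Rsad2, the antiviral protein viperin, at 3.63 against 61.5 CPM, and of 5 complement genes 4 were lower and 1 higher (-2.30, -3.11 to -2.02), with C4b at 6.30 against 52.4 CPM. Microglial markers were lower over whole libraries too, at a median of 0.104 against 13.9 CPM.

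Homeostasis genes of BC11-38 Müller glia had a median of 0.86 (0.84 to 0.90; 12 of 18 higher and 1 lower), clock genes 1.30 (1.25 to 1.39; 12 of 12 higher) with Ciart at 253 against 34.5 CPM, and glycolysis genes 0.67 (0.61 to 0.88; 8 of 13 higher and 1 lower). Lower lists were cell death (-1.29, -1.47 to -1.08; 10 of 14 lower and 1 higher), heat shock (-0.995, -1.04 to -0.95; 9 of 11) and unfolded protein and stress genes (-0.94, -1.17 to -0.88; 14 of 19 lower and 2 higher), where Ddit4, an inhibitor of mTORC1, went the other way at 315 against 28.5 CPM. Of 11082 genes, 1173 were at least 2-fold higher and 1036 lower, against 9.15 from counting noise, and 742 and 1508 under TMM scaling. Under TMM scaling 3 of the 84 list medians given here for rods, cones, cluster 3 and Müller glia turned direction, each with a counting interval that held 0.

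BC11-38 cones had Il18 4.04-fold (2.56 to 6.63), Rab11fip5 3.82-fold (2.42 to 6.29) and Hopx 3.14-fold higher (2.71 to 3.65). Hecw2 had 0 UMIs, at least 33.4-fold lower, Olfm2 was 159-fold lower, from 1 against 132 UMIs (28.1 to 6334), and Rab3b 57.9-fold, from 2 against 96 (15.6 to 485). Cone phototransduction genes had a median of 0.54 (0.51 to 0.56; 6 of 13 higher and 1 lower) with Cngb3 at 493 against 220.1 CPM, immediate early genes -0.67 (-0.82 to -0.52; 6 of 10 lower) and mitochondrially encoded transcripts 0.51 (0.43 to 0.56; 4 of 13 higher). Of 5500 genes, 43 were at least 2-fold higher and 177 lower, and 63 and 145 under TMM scaling. In cluster 3, Pde10a was 4.14-fold (3.33 to 5.19), Mir670hg 3.80-fold (2.88 to 5.06) and Dusp4 3.46-fold higher (2.85 to 4.21), and Serpina3n, Il27 and Prph had 0 UMIs against 1361, 221 and 203, at least 319.7-fold, 51.9-fold and 47.7-fold lower. Its clock genes had a median of 0.40 (0.32 to 0.47; 4 of 15 higher) and its oxidative phosphorylation genes -0.22 (-0.26 to -0.19), and 89 of 7018 genes were at least 2-fold higher and 183 lower.

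**Figure D1:**
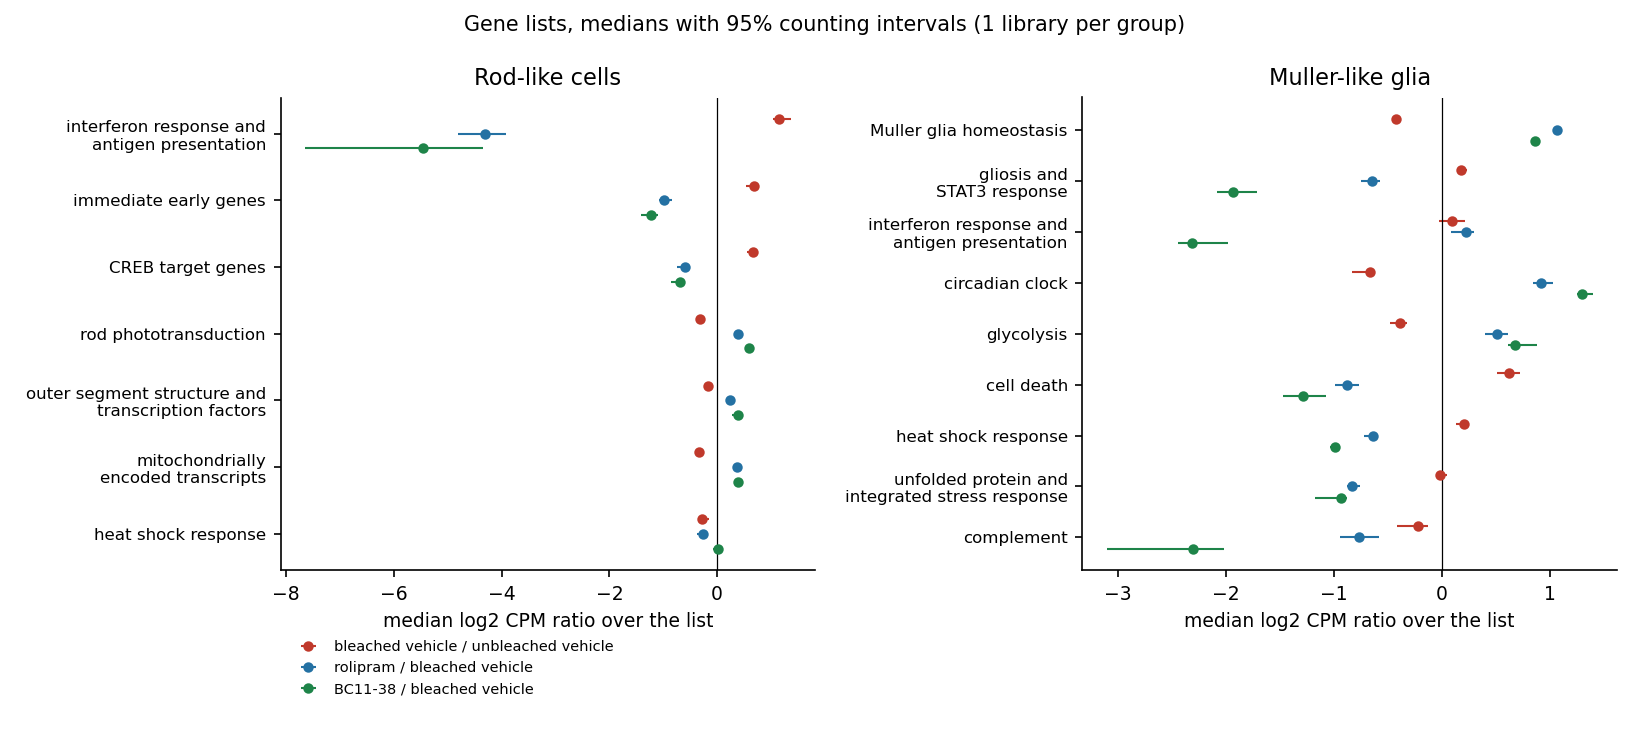
Median log2 CPM ratio (horizontal axis) of each gene list in rods and in Müller glia for bleaching, rolipram and BC11-38, with 95% counting intervals as bars. The rod interferon list lies at 1.15, -4.31 and -5.46, and the Müller homeostasis list at -0.43, 1.07 and 0.86.

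Set side by side at the same dose and day, the 2 drug libraries differed in, among others, the gliosis, interferon and complement transcripts of Müller glia and in Rnf121. In Müller glia Serpina3n was 109.8-fold (46.9 to 339), Ifit1 66.8-fold (30.5 to 183), Rsad2 23.1-fold (13.9 to 41.4) and C4b 10.4-fold higher with rolipram than with BC11-38 (6.996 to 16.1). Rnf121 was 7.44-fold (6.48 to 8.58), Zbtb16, a zinc finger factor, 7.13-fold (5.50 to 9.36), Pde10a 5.23-fold (4.75 to 5.77) and Tsc22d3, a glucocorticoid-induced gene, 4.46-fold lower (3.78 to 5.28). Tsc22d3, like Timp1, lies on chromosome X. Of 21 gliosis genes 18 were at least 1.5-fold higher with rolipram (median 1.10, 0.92 to 1.18), as were 21 of 22 interferon genes (1.49, 1.37 to 1.81), with Gfap, the intermediate filament of reactive glia, at 396 against 32.7 CPM and Ifit3 at 183 against 47.7 CPM. Gfap and Serpina3n are also leading genes of the astrocyte-like cluster seen at Leiden resolution 0.5. It had 21 rolipram and 7 BC11-38 cells, which these Müller values likely include. Microglial markers, at a median of 16.5 against 0.104 CPM over whole libraries, were higher with rolipram too. Complement genes of Müller glia had a median of 1.53 (1.17 to 1.94; 2 of 3 higher), cell death genes 0.45 (0.26 to 0.57; 4 of 11 higher), heat shock genes 0.17 (0.04 to 0.28) and unfolded protein and stress genes 0.17 (0.08 to 0.26). Smaller differences the other way were seen for homeostasis genes (-0.15, -0.17 to -0.12), glycolysis genes (-0.27, -0.30 to -0.13) and clock genes (-0.33, -0.42 to -0.24). Of 9512 genes, 142 were at least 2-fold higher with rolipram and 57 lower.

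In rods Cebpd, a transcription factor of the acute-phase response, was 13.6-fold (8.42 to 23.3), Myo10 3.98-fold (3.11 to 5.14), Gnb3, a cone transducin subunit, 3.69-fold (3.25 to 4.21), Sox30 2.89-fold (2.24 to 3.75) and Stat3 2.65-fold higher with rolipram (2.09 to 3.37). Rnf121 was 7.98-fold (6.41 to 10.0), Col4a3 3.77-fold (2.81 to 5.13), Cd52 2.80-fold (2.09 to 3.79), Hist3h2a 2.74-fold (2.43 to 3.10) and Dnah7b 2.51-fold lower (2.00 to 3.17). Rnf121 stood at 28.3, 29.5, 26.1 and 117 CPM over the whole unbleached, bleached vehicle, rolipram and BC11-38 libraries, so it was above the others in the BC11-38 library alone. Of 4 interferon genes with enough counts, 3 were higher with rolipram (median 0.82, 0.54 to 1.07), and of 13 immediate early genes 4 were higher (0.29, 0.18 to 0.40). Intervals of the other rod lists were -0.14 to -0.09 for phototransduction, -0.09 to 0.03 for outer segment genes, -0.08 to 0.00 for mitochondrially encoded transcripts, -0.09 to 0.22 for CREB targets and -0.41 to -0.18 for heat shock, whose member Cryab stood at 13.3 against 36.5 CPM. Cryab is also a leading gene of the lens-like cluster, with 0 rolipram and 16 BC11-38 cells, so free RNA may add to its rod level. Of 8089 genes, 53 were at least 2-fold higher with rolipram and 22 lower, 29 in all in cells with Y-linked and no Xist UMIs.

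Cones and cluster 3 differed less between the drugs, with 15 of 5379 and 31 of 6449 genes at least 2-fold different. In cones the intervals were -0.12 to 0.00 for phototransduction genes, -0.11 to 0.10 for immediate early genes and -0.29 to -0.25 for mitochondrially encoded transcripts. In cluster 3 they were 0.07 to 0.13 for oxidative phosphorylation genes and -0.32 to -0.12 for clock genes. TMM scaling turned 19 higher and 12 lower genes in cluster 3 into 15 and 17, and 18 and 14 in other bipolar cells into 13 and 22.

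Genes higher after bleaching in rods, Müller glia and cones, and genes lower in Müller glia, lay more often than not beyond the unbleached level in both drug libraries. Over the 122 genes at least 2-fold higher in bleached rods, the median log2 ratio to unbleached rods was 1.19 (1.13 to 1.25) for bleached vehicle, -0.80 (-0.93 to -0.68) for rolipram and -1.49 (-1.66 to -1.35) for BC11-38, with 93 and 100 genes below unbleached. Over 271 such genes in Müller glia it was 1.33 (1.28 to 1.38), -0.24 (-0.31 to -0.17) and -0.73 (-0.84 to -0.65), with 169 and 202 below unbleached. Over the 193 genes lower in bleached Müller glia it was -1.19 (-1.22 to -1.15), 0.42 (0.38 to 0.46) and 0.82 (0.77 to 0.88), with 158 and 164 above unbleached. With 3 counts in place of 0 the drug medians of the higher genes were -0.79 and -1.49 in rods and -0.24 and -0.71 in Müller glia. Over 70 higher genes in cones the medians were 1.31, -0.42 and -0.72, with 44 and 58 below unbleached, over 73 in cluster 3 they were 1.21, 0.10 and -0.09, and over 124 in amacrine cells 1.20, 0.24 and 0.05, with 34 and 58 below unbleached. Most genes lower after bleaching in amacrine and other bipolar cells stayed below unbleached, with 31 and 32 of 147 and 4 and 9 of 37 above it. The make-up of these classes differed between libraries. Amacrine cluster 21 had 320 unbleached and 44 bleached vehicle cells, amacrine cluster 9 had 66 and 121, and bipolar cluster 29 had 91 and 22. Amacrine and other bipolar values may thus reflect which clusters were sampled, which was not tested. With a 1.5-fold limit the rolipram median of the higher rod genes was 0.075, and the 9 lower rod genes (-1.77, -0.43 and 0.41) did not hold direction. They include Xist and Tsix, which are 2 of the 4 lower genes with at least 300 UMIs. Their rolipram median was 0.22 with a minimum of 300 UMIs, and their BC11-38 median -0.10 under TMM scaling and -0.31 with genes chosen and measured on separate cells.

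**Figure D2:**
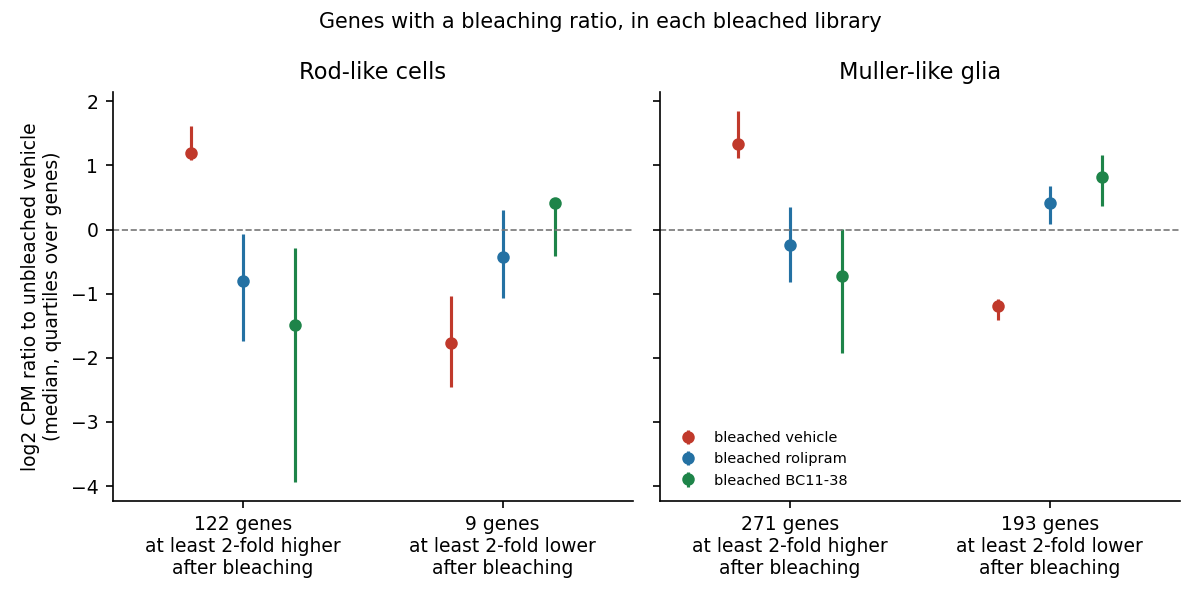
Log2 CPM ratio to the unbleached library (vertical axis) of the bleached vehicle, rolipram and BC11-38 libraries, as medians and quartiles over the genes at least 2-fold higher or lower after bleaching in rods and Müller glia. Medians of the higher rod genes are 1.19, -0.80 and -1.49.

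The bleached vehicle library enters the bleaching ratio and both drug ratios, which alone makes the ratios oppose each other. Across genes in rods, Pearson's r between the drug and bleaching log2 ratios was -0.70 for rolipram and -0.72 for BC11-38, against -0.53 simulated for each without any difference between groups, and the covariance was -0.143 and -0.191 against -0.0151 and -0.0152 simulated. In Müller glia r was -0.81 and -0.77 against -0.26 and -0.21, and the covariance -0.313 and -0.413 against -0.00604 and -0.00595. With separate bleached vehicle cells for each ratio, which removes the shared counting error but not what the cells of a library share, r was -0.56 and -0.62 in rods and -0.76 and -0.75 in Müller glia. Genes are not independent replicates. Of 108 genes higher after bleaching in rods and counted with rolipram, 82 were lower with it, and of 106 counted with BC11-38, 91 were lower. In Müller glia 212 of 269 and 227 of 267 were lower. These overlaps include what the shared library adds.

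Shares of cells with a UMI followed the same order as the levels. After every rod was thinned to 750 UMIs, Edn2, an endothelin of stressed photoreceptors, was seen in 4.15% of unbleached, 11.1% of bleached vehicle, 2.21% of rolipram and 0 of 2090 BC11-38 rods, which allows up to 0.144% of rods with a UMI at that depth. The unthinned shares were 9.09%, 21.4%, 3.49% and 0.219%, and 102, 74, 103 and 188 shallower rods were left out. At 750 UMIs cluster 3 cells, which should lack the gene, had it in 0.345%, 0%, 0% and 0% (unthinned 0.341%, 1.85%, 0.166% and 0%). With Müller glia thinned to 2000 UMIs, Gfap was seen in 30.98%, 46.8%, 11.8% and 1.77% (unthinned 55.9%, 72.5%, 19.2% and 2.83%) and Lcn2 in 7.07%, 13.7%, 1.78% and 0.177% (unthinned 10.6%, 23.1%, 3.06% and 0.333%), with 44, 64, 86 and 35 cells left out. Cluster 3 had Gfap in 0.357%, 1.34%, 0% and 0% (unthinned 1.71%, 3.88%, 0.333% and 0%). It had Lcn2 in 0%, 0.382%, 0% and 0% (unthinned 0%, 1.11%, 0% and 0%). Median UMIs in the 4 libraries were 1668, 1528, 1235 and 1399.5 in rods, 11580, 13694, 5589 and 6782 in Müller glia and 7347, 6866, 4517 and 5595 in cluster 3. CPM of Edn2 in rods was 63.8, 172, 28.8 and 1.66, and in Müller glia Gfap stood at 764, 869, 396 and 32.7 CPM and Lcn2 at 180, 360.4, 58.4 and 2.18 CPM.

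**Figure D3:**
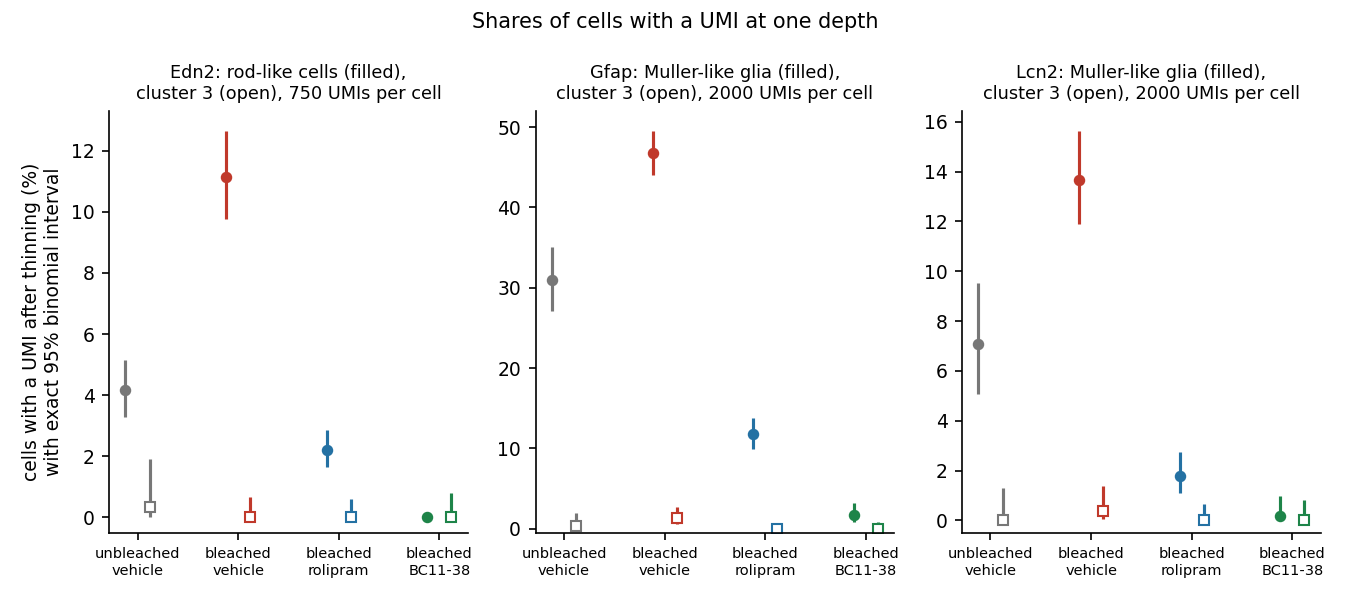
Percent of cells with a UMI (vertical axis) for Edn2 in rods thinned to 750 UMIs and for Gfap and Lcn2 in Müller glia thinned to 2000 UMIs, in each library, with exact 95% binomial intervals; open points are cluster 3 cells. Gfap is seen in 30.98%, 46.8%, 11.8% and 1.77% of Müller glia.

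Transcripts of the drug targets were counted in all 4 libraries, with Pde11a and Pde4c at low levels. Over all cells of the unbleached, bleached vehicle, rolipram and BC11-38 libraries, Pde4a stood at 34.6, 18.6, 37.8 and 35.7 CPM, Pde4b at 68.6, 44.0, 72.8 and 75.9 CPM, Pde4d at 37.9, 20.1, 27.9 and 37.8 CPM and Pde4c at 0.761, 0.721, 0.983 and 1.04 CPM. Pde11a stood at 2.28, 0.541, 0.539 and 0.483 CPM and Pde2a at 9.49, 22.8, 6.63 and 6.73 CPM. Counting intervals of the bleached vehicle values were 17.4 to 19.9 for Pde4a and 0.346 to 0.805 for Pde11a, whose unbleached interval was 1.81 to 2.84. Amacrine cells, whose share was lowest in bleached vehicle, held 56.0 to 78.8 CPM of Pde4a and rods 1.66 to 4.62 CPM. The 2 deleted genes were counted too, Abca4 at 43.7, 43.4, 56.7 and 57.1 CPM and Rdh8 at 0.930, 0.406, 0.697 and 0.483 CPM. Tags from the 3' end can lie outside the deleted part, so these levels do not check the genotype.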

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

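Of the tests below, that of free RNA summed over the list in rods was written before its result was seen. The other tests, of even uptake, of single list members, of Müller RNA in rods, of sex make-up, of transcripts or cells from another library, of exchanged names, of depth and of doublets, were chosen after the results were seen. A depth test written before is left out, since it used the named genes alone, which have the largest ratios.

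Transcripts outside the comparisons differed between libraries. Haemoglobin stood at 639.8 CPM in the bleached vehicle library and at 6.56 in the BC11-38 library, above the unbleached library (1.46), and rolipram had 1.30. Lens-like cells numbered 4 in the bleached vehicle and 16 in the BC11-38 library, and 0 in the other libraries. Both were picked out because the unbleached library, taken as control, had less. No explanation was tested.

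Interferon-response transcripts in bleached vehicle rods were weighed against RNA of other cells and sex make-up, and even uptake of free RNA was argued against, since the tenth of rods with most held 56.1% of the list's UMIs, against a mean of 27.2% in 100 draws by depth alone. For 7 members (Stat2, Irf7, Irf9, Bst2, Gbp3, Tap1 and Usp18 of 16), UMIs per rod exceeded those per cell of each other neuron class beyond counting intervals. Free RNA from those classes, if taken up in like amounts by all cells, was argued against for these 7 alone, which were picked by this outcome. Müller glia held more UMIs per cell than rods for 6 of the 7, but at the largest share of a Müller cell per rod that their markers allow (0.71%) they could give at most 6.71% of any of the 7, so they were argued against as the source. Over the whole list, in the test written before, UMIs per rod were 0.878 times those of the highest other class. They were 2.73 per rod, below 3.11 per cone and 3.08 per amacrine cell, as free RNA would give. They lay above 2.18 per other bipolar cell and 1.65 per cluster 3 cell. The sum thus does not decide, and free RNA may account for the other 9 members. In rods with Y-linked and no Xist UMIs the median was 0.50 (0.37 to 0.70) over 8 members with enough counts. For the same 8 in all rods it was 1.11 (1.03 to 1.27). The ratio thus stayed above 0 with sex held fixed but was smaller, so the parts of sex make-up and bleaching cannot be told apart. With 2 mice per library, cells of 1 sex may come from 1 mouse, so sex cannot be told from the mouse either. A biological effect of light remains untested because each group had 1 library.

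Gliosis transcripts of Müller glia were higher in the unbleached library than in both drug libraries. Cells of the bleached vehicle library, which has almost no Xist cells, were argued against as the only source, since Gfap was seen in 19.8% of thinned unbleached Müller cells with Xist (15.1 to 25.2%) and in 1.96% of BC11-38 cells with Xist (0.723 to 4.22%), and cells of 1 sex alone too, as it was seen in 39.1% of unbleached cells without Xist (33.5 to 45.0%). Of the 16 gliosis members above both drug libraries, 13 had fewer UMIs per cluster 3 cell than per Müller cell at 2000 UMIs beyond counting intervals. The median cluster 3 level was 0.625% of the Müller level. Free RNA of the bleached vehicle library was thus argued against as the source of the whole Müller level of these 13, and may add to the other 3. Genes of glia would pass this in any case. Their excess over the drug libraries was not compared with the cluster 3 level, so a part from free RNA stays open. An exchange of the unbleached and BC11-38 library names could also give this order, and the median log2 ratio of 1.46 between them, unbleached over BC11-38, does not decide it because a true difference would give it too. Stress of tissue handling, which may differ by library, stays open untested, as does an effect of both drugs below the unbleached level.

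Müller ratios of both drugs to bleached vehicle were weighed against depth, sex and doublets. At least 94.9% of the median log2 ratio over all genes at least 2-fold different was kept after thinning, for both drugs and directions. The heavier weight of deep cells in the sums thus did not set the ratios. Deeper Müller cells in the bleached vehicle library are not excluded otherwise, because random thinning leaves the make-up of each cell unchanged. Sex make-up as the whole cause was argued against, since at least 91.9% of the median log2 ratio was kept in cells with Y-linked and no Xist UMIs, for both drugs and directions. Without the highest doublet scores 96.9% of genes stayed at least 2-fold different. This does not exclude doublets, because the caller found few of those expected and its scores may miss them. These ratios may reflect the drugs, but depth and doublets stay open. Batch, handling and the state of 2 mice in the bleached vehicle library are confounded with treatment.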

How the results depend on the processing

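Tests with thinned cells for gene counts, the unnamed cluster counted as rods, cells with Y-linked and no Xist UMIs, cells without the highest doublet scores and the second naming rule were chosen after the data were seen, and the other alternatives before. Counts below are of genes at least 2-fold different in rods, cones, Müller glia and cluster 3. As reported they were 131, 77, 464 and 100 after bleaching, 269, 183, 1620 and 214 with rolipram, 439, 220, 2209 and 272 with BC11-38, and 75, 15, 199 and 31 between the drugs.

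All 24 gene counts, higher and lower together, stayed within 1.5 times under TMM scaling, the mean over cells of counts per 10000, doublets kept and removal of the highest doublet scores. Of 292 values of gene counts over all alternatives, 163 were within 1.5 times and 129 were not. Of 1006 values of the 120 named ratios, 808 stayed within their counting interval, 197 moved in the same direction and 1 reversed. Of 670 values of the 84 list medians in the text, 432 stayed, 223 moved and 15 reversed. The 3 medians that turned direction under TMM scaling, each with a counting interval that held 0, are not among these 15. Lists not in the text gave 1953 values, of which 1507 stayed, 408 moved and 38 reversed. Of 124 values of cell shares 87 stayed and 37 moved, and of 48 values of position 16 stayed, 28 moved and 4 reversed. In cells with Y-linked and no Xist UMIs, 82 of 84 list medians gave a value.

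A minimum of 30 UMIs gave, after bleaching, 397 genes in rods, 321 in cones, 838 in Müller glia and 397 in cluster 3. With rolipram it gave 579 in rods, 488 in cones and 533 in cluster 3, with BC11-38 883, 546 and 694 in the same classes, and between the drugs 275 in rods, 143 in cones, 474 in Müller glia and 214 in cluster 3. More genes of few counts enter, so the count is higher by construction.

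A minimum of 300 UMIs gave, after bleaching, 42 in rods, 15 in cones, 266 in Müller glia and 27 in cluster 3. With rolipram it gave 123, 56, 1051 and 91 in these classes, with BC11-38 203 in rods, 75 in cones and 108 in cluster 3, and between the drugs 19, 2, 98 and 9 in rods, cones, Müller glia and cluster 3. Fewer genes enter by construction. Position over the lower rod genes was -5.69 for bleached vehicle, 0.22 for rolipram (reversed from -0.43) and 0.58 for BC11-38, over 4 genes of which 2 are Xist and Tsix. Over the higher Müller genes it was 1.25 for bleached vehicle and -0.33 for rolipram, and over the lower Müller genes -1.13 for bleached vehicle, and the cause was not tested.

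A 1.5-fold limit gave, after bleaching, 621, 424, 1735 and 555 genes in rods, cones, Müller glia and cluster 3. It gave 867, 690, 4026 and 748 with rolipram, 1416, 762, 4634 and 941 with BC11-38, and 440, 211, 710 and 343 between the drugs, more by construction. Position over the higher rod genes was 0.73, 0.075 and -0.20 for bleached vehicle, rolipram (reversed from -0.80) and BC11-38, and over the lower rod genes -0.68 for bleached vehicle and 0.0106 for BC11-38. Over the higher Müller genes it was 0.81, -0.16 and -0.42, and over the lower Müller genes -0.79, 0.30 and 0.57. Genes with smaller ratios enter by construction.

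With the class mean of the log values, counts after bleaching were 1 in rods, 0 in cones, 0 in Müller glia and 1 in cluster 3. They were 5, 6, 4 and 4 with rolipram, 7, 2, 8 and 3 with BC11-38, and 1, 1, 0 and 2 between the drugs. A mean of logs over cells that mostly hold 0 compresses ratios by construction. List medians that reversed were mitochondrially encoded transcripts in cones, 0.20 after bleaching (reported -0.52) and -0.073 with BC11-38 (0.51), interferon genes in Müller glia with rolipram, -0.047 (0.22), and oxidative phosphorylation genes in cluster 3, 0.22 with rolipram (-0.10) and 0.10 with BC11-38 (-0.22). Between the drugs, rod phototransduction genes were at 0.0072 (-0.12), cone phototransduction genes at 0.13 (-0.06), mitochondrially encoded transcripts in cones at 0.24 (-0.26), and in Müller glia unfolded protein genes at -0.025 (0.17), homeostasis genes at 0.11 (-0.15) and glycolysis genes at 0.0152 (-0.27). The cause of these reversals was not tested.

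Cells thinned to 1 depth gave 73, 18, 195 and 40 genes after bleaching, 160, 64, 942 and 101 with rolipram, 277, 73, 1068 and 111 with BC11-38, and 43 in rods, 9 in cones and 91 in Müller glia between the drugs. Thinning removes UMIs, so fewer genes reach the minimum by construction.

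Cells with Y-linked and no Xist UMIs gave, after bleaching, 43 genes in rods, 28 in cones and 62 in cluster 3. In rods they gave 160 with rolipram, 290 with BC11-38 and 29 between the drugs. Gria2 after bleaching in rods was at 0.22 (reported -0.67) and heat shock genes between the drugs in Müller glia at -0.022 (0.17). Fewer cells enter, and whether sex, mouse or depth set these values was not tested, so the cause was not tested.

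Under the second naming rule 70 genes differed in rods after bleaching and 179 with rolipram. Amacrine shares were then 20.2%, 5.57%, 13.4% and 16.4% and rod shares 26.6%, 24.4%, 24.1% and 25.7% in the unbleached, bleached vehicle, rolipram and BC11-38 libraries, since cluster 9 is then named horizontal in place of amacrine and rod clusters 1 and 5 are unnamed, by construction.

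With the mean over cells of counts per 10000 the complement median in Müller glia after bleaching was 0.069 (-0.23), and the cause was not tested. With genes higher in rods kept, the Müller interferon median with rolipram was -0.16 (0.22) and the Müller glycolysis median between the drugs 0.0104 (-0.27), because more members enter.

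Position with genes chosen on 1 random part of the bleached vehicle cells and measured on the rest was 1.07, -0.67 and -1.21 over the higher rod genes for bleached vehicle, rolipram and BC11-38. It was -0.92 for bleached vehicle and -0.31 for BC11-38 (reversed from 0.41) over the lower rod genes, and -1.12 for bleached vehicle over the lower Müller genes. Under TMM scaling it was 1.38, -1.12 and -1.72 over the higher rod genes, and -1.16 for bleached vehicle and -0.10 for BC11-38 (reversed) over the lower rod genes. Over the higher Müller genes it was -0.38 for rolipram and -0.89 for BC11-38, and over the lower Müller genes 0.28 and 0.69, and the cause was not tested.

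As shares of non-rod cells, Müller glia were 18.0%, 32.8%, 23.1% and 15.6%, amacrine cells 36.6%, 11.6%, 22.0% and 27.9%, and microglia-like cells 0.422%, 0.883% and 0.612% in the unbleached, bleached vehicle and rolipram libraries, by construction. With at least 500 UMIs and at most 10% mitochondrial UMIs, amacrine shares were 22.5% in the unbleached and 19.2% in the BC11-38 library, and the cause was not tested. Rod shares were 30.9% and 30.3%. There a shallow cluster with rod markers stayed unnamed, with 644 unbleached and 541 BC11-38 cells, against 396 and 14 unnamed cells in the main clustering. Without the highest doublet scores microglia-like shares were 0.0552% in the unbleached and 0.0676% in the rolipram library. Rod shares in the unbleached, bleached vehicle and rolipram libraries were 41.7%, 36.8% and 33.4% with doublets kept, and 41.7%, 36.8% and 33.5% at Leiden resolutions 0.5 and 2 and with the unnamed cluster counted as rods, because that cluster is then named rod.

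Depth limits what can be said of genes with few counts. With 100 UMIs over both libraries as the minimum, 8310 genes were compared in rods after bleaching and 11205 in Müller glia. Genes at 0 in 1 library have bounds and no ratio, and microglia-like cells were too few in every library for ratios.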

Other observations

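Tests of how interferon UMIs are spread over rods were chosen after the result was seen.

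Gnb3, a subunit of cone transducin, stood at 570, 1026, 311 and 84.1 CPM in rods of the unbleached, bleached vehicle, rolipram and BC11-38 libraries. In cones it stood at 3966, 4339, 4218 and 3788 CPM. Its order in rods was not particular to them, with 1833, 2862, 1806 and 1473 CPM in cluster 3 and 1119, 1727, 1083 and 859 CPM in other bipolar cells. Cebpd in rods stood at 233, 423, 67.7 and 4.98 CPM and Stat3 at 140, 199, 71.8 and 27.1 CPM. Pde10a in Müller glia stood at 62.4, 19.6, 76.7 and 401 CPM and Serpina3n at 229, 255, 133 and 1.21 CPM.

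Rnf121 was higher in the BC11-38 library in every class compared. It stood at 32.4, 32.8, 25.01 and 199.5 CPM in rods, 34.8, 35.7, 34.6 and 258 CPM in Müller glia, 22.4, 20.6, 17.2 and 91.7 CPM in cluster 3 and 27.0, 21.8, 24.7 and 73.7 CPM in amacrine cells. In cones it stood at 23.9, 30.0, 22.8 and 59.7 CPM. No explanation was tested.

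In the bleached vehicle library, 38.5% of rods held no UMI of the interferon list, where draws by depth alone give 11.02%. Gbp7 stood at 71.8 CPM over all rods of that library, 50.3 CPM in Müller glia and 1.73 CPM in cones, and Irgm1 at 98.5 CPM in rods and 20.9 CPM in Müller glia. This is consistent with a subset of rods carrying these transcripts, as the tenth with most held 56.1%, but the test did not separate rods by any other property.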
